A study of Homo sapiens with 12 samples.

How the data were processed

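The 12 samples were total RNA of PANC-1 cells with an empty vector (6 control) or with a hairpin against TIMP1 (6 knockdown), and groups and replicate numbers were taken from the sample titles. The titles call the control samples WildType and do not name the vector. Per the labels' protocols, cells were grown in medium with puromycin, RNA was isolated with a column kit, and labelled cRNA was made with an Illumina amplification kit. The deposited values were of 2 kinds. The non-normalised table held, per the file headers, a linear signal intensity of each probe on each array, ranging from 98.3 to 19220 over the 12 arrays, and a detection p-value for each, which compares the probe with the array's negative controls. The software that made the table and the method of the detection p-values are not given in the sources used here. The authors' processed table held a normalised intensity per probe. Its values equalled a quantile normalisation of the linear signal to within 3.33e-06, with a median of 188.8 in every column, so they were on a linear scale, not centred, and in the direction of the signal. The submitters' processing notes name limma without its role. All columns of per-sample values were assigned to a sample.

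The non-normalised signals were background corrected and normalised with the neqc function of limma 3.58.1 in R 4.3.3. It fits a normal plus exponential model with negative controls inferred from the detection p-values, adds an offset of 16, applies quantile normalisation and takes log2. The offset pulls fold changes of dim probes towards 0, and quantile normalisation removes any shift common to all probes. Probes were kept when their detection p was under 0.05 on at least 6 of the 12 arrays, which left 16495 of 47323. Of all probes, 30113 had 1 gene symbol in the platform annotation, 8 had several and 17202 were unnamed here; symbols were updated by gene number through a RefSeq gene table of assembly GRCh38.p14 for 30074 probes and kept otherwise. No gene was named from a probe with several symbols. The array's genome build is not given in the sources used here, so no coordinates are printed. Each gene was represented by its detected probe with the highest mean log2 intensity, and 9780 genes had one.

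Group differences were tested per probe with lmFit and eBayes of limma on the group term alone, over all 12 arrays, with Benjamini-Hochberg adjustment over the detected probes and a threshold of 0.05. All p-values are two-sided. The difference in TIMP1 was also tested with an exact permutation test over the 924 assignments of 12 arrays to groups of 6. Log2 fold changes are knockdown minus control, with standard errors and 95% confidence intervals from the moderated fit. Gene lists were tested with camera (inter-gene correlation 0.01) on 1 probe per gene against all detected genes, with fry and camera with an estimated correlation beside it, adjusted over the lists with at least 3 detected members. A probe detected on no array of a group was given only a bound, the mean of the brighter group against the mean, per array of the other group, of the higher of the lowest detected signal and its own.

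The tests, the 25 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named as later choices. The rule named TIMP1, the 12 genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05 whose groups did not overlap, leaving out unnamed and provisional symbols, and in each list up to 4 members with the smallest p. There were 5 such fallers, 1 of which is not reported here. The alternatives were no background correction, a plain normexp correction with an offset of 50, cyclic loess or median scaling in place of quantile normalisation, the authors' processed values, no detection filter or a stricter one (p under 0.01 on all 12 arrays), the replicate number as a block, an intensity trend with a robust fit, array weights, a Wilcoxon test, a threshold of 0.01, leaving out each array, and for lists the estimated correlation, fry and the mean of all probes of a gene.

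The fit was tested on simulated data for the comparison of TIMP1 knockdown with control, with the real means and residual spread of 16495 probes and independent errors. Of 200 changed probes, 40 per size, it recovered 5 of 40 at a log2 fold change of 0.2, 29 at 0.4, 36 at 0.6, 37 at 0.8 and 39 at 1, with 3 false calls, and the 1 list that had been shifted by 0.3 was the 1 list called. These counts may not hold for the real arrays. There the estimated correlation between genes reached 0.414, in the list of the unfolded protein and integrated stress response. The largest absolute median log2 fold change of a real list was 0.12. Figures were drawn with matplotlib 3.10.9.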

Results

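Gene expression was measured in PANC-1, an established human cell line from a carcinoma of the pancreatic duct, on 12 Illumina bead arrays hybridised with biotin-labelled cRNA. In 6 samples the cells carried an integrated empty pLKO.1 lentiviral vector (control), and in the other 6 they carried the same vector with a short hairpin RNA against TIMP1 (knockdown). TIMP1 is a secreted inhibitor of matrix metalloproteinases. The labels name replicates 1 to 6 in each group but do not say that these came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Each array held 47323 probes, of which 16495 were detected (detection p under 0.05 on at least 6 of the 12 arrays), covering 9780 named genes. Between 15681 and 16565 probes were detected per control array and between 15898 and 17680 per knockdown array. The knockdown arrays had more detected probes on average, 16861 ± 641 (SD, n = 6) against 16160 ± 350 (n = 6; exact two-sided permutation p = 0.0498). The number of arrays limits the precision of the values.

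The first comparison asked by how much the hairpin lowered its target. TIMP1, on the X chromosome and represented by 1 probe, was lower in each of the 6 knockdown samples than in any of the 6 controls. Its normalised log2 intensity was 13.56 ± 0.06 (SD, n = 6) in the knockdown and 13.75 ± 0.07 (n = 6) in the controls, and the log2 fold change was -0.19 (95% confidence interval -0.29 to -0.10). On the linear scale TIMP1 fell by 12.5%. The controls alone ranged from 13.64 to 13.86, as wide as the difference between the groups. The slides and the order in which the samples were handled are not given in the sources used here, so a difference in handling is not separated from the group difference, nor excluded by the permutation p. The lowest control was control 6 and the highest knockdown array was knockdown 1; if the replicate numbers followed the order of handling, which the labels do not say, a drift over that order could give the same separation. The exact two-sided permutation p of 0.00216 is the smallest that 6 arrays against 6 can give. Over all detected probes the Benjamini-Hochberg adjusted p from limma was 0.101, and it lay between 0.0249 and 0.517 over 26 alternative settings. TIMP1 remained among the brightest probes in both groups, with 34 to 204 of the 47323 probes brighter on the control arrays and 211 to 343 on the knockdown arrays. With scaling by the median alone, which raised the median of all detected probes by 0.12 in the knockdown, the log2 fold change of TIMP1 was -0.12 (exact permutation p = 0.119), or -0.24 relative to that median.

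**Figure D1:**
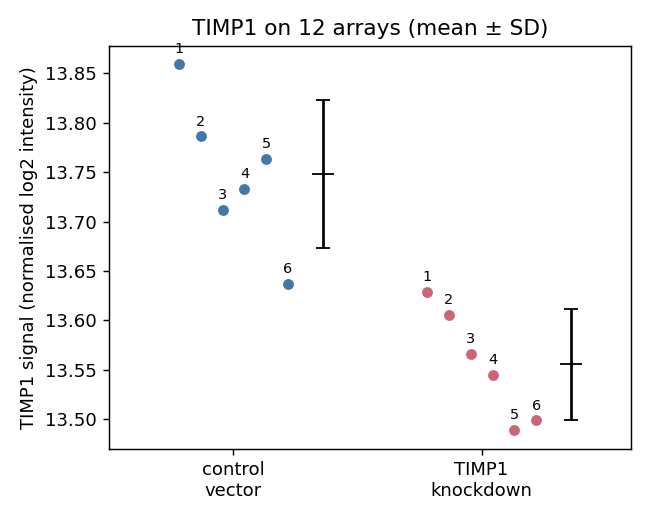
Normalised log2 intensity of the TIMP1 probe on each array (points, with the replicate number of the label) for the control vector and the TIMP1 knockdown, with the mean and SD of the 6 arrays as a bar beside them. The lowest control array, at 13.64, lies just above the highest knockdown array, at 13.63.

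The second comparison asked which other transcripts differed between knockdown and control cells. The largest rises past the threshold were those of OLR1, a receptor for oxidised low-density lipoprotein, with a log2 fold change of 1.31 ± 0.20 (SE, n = 6 per group; limma adjusted p = 0.0342), and of SPRR2A, a small proline-rich protein of the cornified envelope, with 1.07 ± 0.15 (adjusted p = 0.0192). S100A9, a calcium-binding protein secreted as part of calprotectin, rose by 0.93 ± 0.12, from 10.28 to 11.21 (adjusted p = 0.0169). The largest fall past the threshold was that of RERG, a Ras-like GTPase, which changed by -0.74 ± 0.12 (limma adjusted p = 0.0415). S100A9 ranged from 9.99 to 10.65 over the controls alone. For S100A9, OLR1 and SPRR2A control 6 was the highest control and knockdown 1 the lowest knockdown array. They lay at 10.65 and 10.89, 7.50 and 7.62, and 6.90 and 7.08. For RERG the nearest arrays were control 5 at 7.16 and knockdown 1 at 7.09. A drift over an order of handling, which is not given in the sources used here, was not tested for these genes. The sizes of dim genes, and with them the order of the changes, depended on the background correction. Without it the log2 fold change was 0.71 for OLR1, 0.54 for SPRR2A, 0.85 for S100A9 and -0.37 for RERG. S100A9 then exceeded OLR1 and SPRR2A, and RERG no longer had the largest fall.

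Of the 16495 detected probes, 42 were higher and 8 were lower in the knockdown (limma, Benjamini-Hochberg adjusted p under 0.05). Judged by the brightest probe of each gene, 38 genes passed, 33 higher and 5 lower. Of the other called probes, 4 had no gene symbol. MPZL2, ANKRD22, CD83, ARID2 and DIAPH3, all higher, and TMEM14C and LYPD6B, both lower, were called on a dimmer probe only. The brightest probe of each of them did not pass, and they are not counted among the 38. In 33 of the 38 genes, 28 of them higher and 5 lower, no knockdown array overlapped any control array. Over all detected probes such separation occurred for 1.56%, against 0.216% by chance. The changes were small: 16 of the 50 probes changed by 1.5-fold or more and 4 by 2-fold or more, all 4 of them higher. These were the probes of OLR1, SPRR2A and S100A8 and an unnamed probe, ILMN_1705066. Without background correction 0 probes were called at least 2-fold higher. S100A8 and the unnamed probe fell outside the rule for named genes and were chosen after their values were seen. By limma 0 probes were at least 2-fold lower, also 0 at an unadjusted p under 0.05, and the lowest log2 fold change of a detected probe was -0.97. At an unadjusted limma p under 0.05 there were 2390 probes, 1454 higher and 936 lower, where 825 would be expected by chance for independent probes. Among 100 divisions of the same arrays into 6 and 6, this one included, the others gave a median of 651 such probes and at most 2287.

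Among the other risers, the secreted metalloproteinase ADAMTS9 had a log2 fold change of 0.76 ± 0.10 (SE) and the secreted cysteine protease inhibitor CST1 one of 0.64 ± 0.10. IL11, a cytokine that signals through gp130, rose by 0.64 ± 0.10, and IL13RA2, a decoy cytokine receptor, by 0.59 ± 0.10. COL8A1, a collagen chain, rose by 0.47 ± 0.08 on its brightest probe; its other 2 detected probes gave 0.67 (adjusted p = 0.0403) and 0.46 (adjusted p = 0.0792). DNAAF3, a factor for the assembly of dynein arms, rose by 0.66 ± 0.12, the formin DIAPH2 by 0.55 ± 0.10, and LRP3, of the low-density lipoprotein receptor family, by 0.48 ± 0.06. SPRR2F rose by 0.76 ± 0.12, but the SPRR2 genes are near-identical copies whose probes may cross-hybridise, so the rise cannot be assigned to one of them with certainty. OLR1 was detected on 4 and SPRR2A on 2 of the 6 control arrays, and both on all 6 knockdown arrays, so their fold changes start from near the background. Among the other fallers were STX1A, a syntaxin of vesicle fusion, at -0.34 ± 0.05, the serine protease inhibitor SPINT2 at -0.26 ± 0.05, and KCTD20 at -0.23 ± 0.04. The limma adjusted p of these genes lay between 0.0169 and 0.0479, and for each of them all 6 knockdown arrays lay beyond all 6 control arrays. An adjusted p under 0.05 and this separation were conditions of the rule that named them, so they add no further support. Without background correction ADAMTS9 had 0.47, SPRR2F 0.39, DNAAF3 0.40 and DIAPH2 0.27, and DIAPH2 and KCTD20 were no longer past the threshold. With scaling by the median alone OLR1, SPRR2A, S100A9, ADAMTS9, SPRR2F, IL11 and RERG remained past it, and DNAAF3, CST1, IL13RA2, DIAPH2, LRP3, COL8A1, STX1A, SPINT2 and KCTD20 did not.

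The number of calls depended on single arrays. Without control 6 there were 63 calls and without knockdown 1 there were 145, while leaving out any other single array left fewer: 1 without control 1, 8 without control 2, 1 without control 3, 2 without control 4, 7 without control 5, 7 without knockdown 2, 7 without knockdown 3, 1 without knockdown 4, 5 without knockdown 5 and 8 without knockdown 6. The 4 probes at least 2-fold higher became 5 without control 6, stayed at 4 in number without knockdown 1 and became 0 without any other single array. With the number of detected probes per array as a covariate, an alternative chosen after seeing the data, limma called 0 probes at an adjusted p under 0.05 (1152 at an unadjusted p under 0.05), and all 50 probes kept their direction, with a median absolute log2 fold change of 0.37 in place of 0.40. Without knockdown 2 and 6, also chosen after seeing the data, 1 probe was higher and 1 lower, and none of the genes named so far passed.

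**Figure D2:**
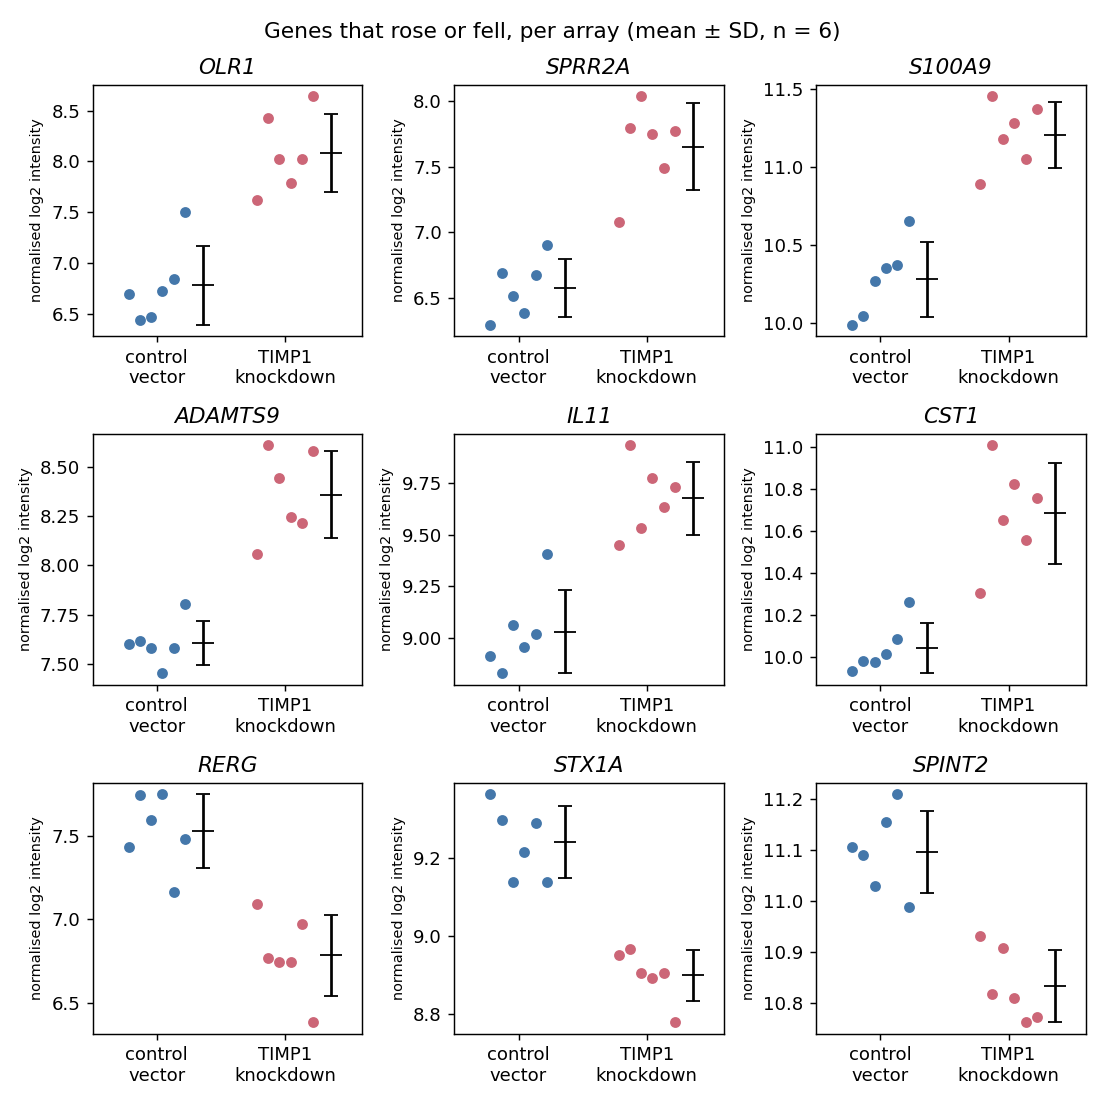
Normalised log2 intensity per array (points) of 6 genes that rose and 3 that fell in the TIMP1 knockdown, with the mean and SD of the 6 arrays of each group as a bar beside them. In each panel the knockdown arrays do not overlap the control arrays, as the rule for named genes required. OLR1 has the largest log2 fold change, 1.31.

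**Figure D3:**
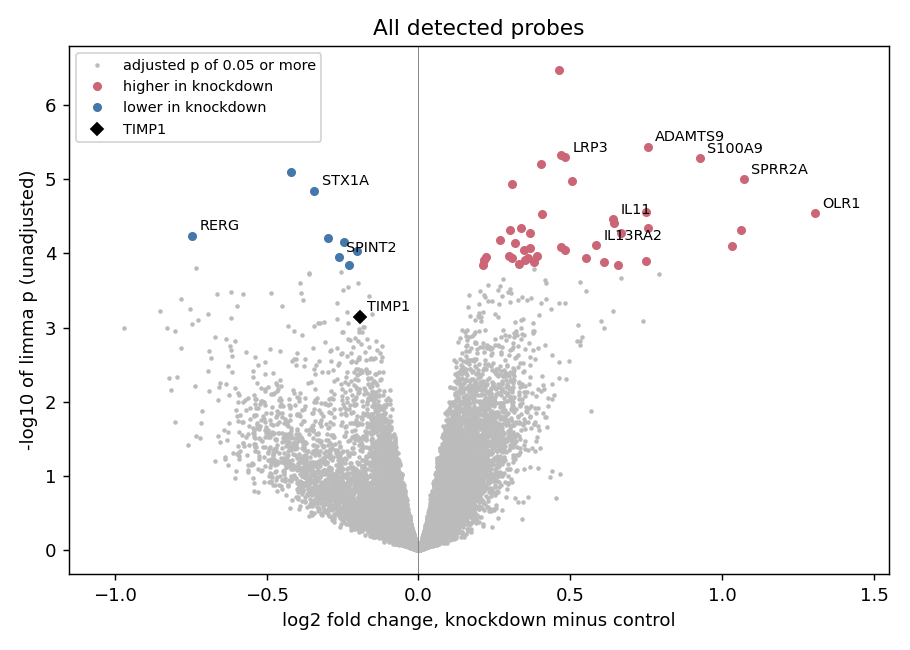
Log2 fold change (knockdown minus control, horizontal axis) and minus log10 of the unadjusted limma p (vertical axis) of the 16495 detected probes, with the 42 probes that were higher and the 8 that were lower at an adjusted p under 0.05 in colour. TIMP1, the black diamond, has a log2 fold change of -0.19 and lies below the called probes.

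The third comparison asked whether groups of genes moved together. Of 481 genes in 25 lists, 322 were detected, and 2 of these passed the threshold over all probes, IL11 and BIK, both higher. No list was shifted by limma's camera test after adjustment over the 24 lists that had at least 3 detected members (smallest adjusted p = 0.0906; 2 lists at an unadjusted p under 0.05), and none with an estimated correlation. Without knockdown 3 camera called 1 list, that of NRF2 targets and metallothioneins (adjusted p = 0.0284; between 0.00649 and 0.393 over its alternatives); with all arrays and an estimated correlation its adjusted p was 0.308. The fry test, which asks whether the genes of a list move on balance one way, called 0 lists (smallest adjusted p = 0.0843), and its mixed form, which asks whether they change in either direction, called 11; neither compares a list with other genes. In 9 of the 24 lists knockdown 2 and knockdown 6, which also had the most detected probes, had higher means than the other 10 arrays: TIMP1 partners and focal adhesion, p53, apoptosis, interferon, NF-kB, hypoxia, stress response, leukocyte and endothelial, and oxidative phosphorylation.

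Among metalloproteinases and their inhibitors, none of the 13 detected genes of the list passed the test, also when adjusted over the list alone. The metalloproteinase ADAMTS9, which rose, was not in the list. TIMP3 had a log2 fold change of 0.18 ± 0.06 (SE; adjusted p = 0.24), ADAM10 one of -0.11 and TIMP2 one of 0.09. None of the 19 detected TIMP1 surface partners and focal adhesion genes passed over all probes or adjusted over the list alone. PTK2, the focal adhesion kinase, had 0.10 (limma adjusted p = 0.199) and ITGA6 had 0.19. CD63 and LRP1, also in that list, were not among the detected genes. Of 10 extracellular matrix genes none passed over all probes, and 4 did when adjusted over the list alone; the collagen gene COL8A1, which rose, was not in the list. These were AGRN at -0.25 and COL4A2 at -0.51 (-0.27 without background correction), both lower, and TNC at 0.19 and TGFBI at 0.17, both higher. None of 11 TGF-beta and BMP targets passed either way, with KLF10 at 0.20 and CCN2 at -0.13. Of 13 epithelial markers none passed over all probes, and 1, MAL2, was lower at -0.60 (-0.31 without background correction) adjusted over the list alone; EPCAM had -0.10. None of the 9 mesenchymal markers passed either way, and AXL had 0.15.

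Gemcitabine is a nucleoside drug named in the title of the series. None of the 17 detected genes of its transport and metabolism passed over all probes or adjusted over the list alone. The transporters SLC29A1 and SLC28A3 and SAMHD1, also in the list, were not among the detected genes, so this result does not cover them. CDA, the deaminase that inactivates gemcitabine, had a log2 fold change of 0.18 ± 0.06 (SE; adjusted p = 0.232), and the uptake transporter SLC28A1 had 0.36 ± 0.13 (adjusted p = 0.261), or 0.18 without background correction and 0.24 without knockdown 2 and 6; CDA had 0.11 without these 2 arrays. None of 19 mitotic cell cycle genes and none of 19 DNA replication genes passed either way; PLK1 had 0.13 and CDC45 had 0.15. In the p53 and DNA damage list 0 of 13 genes passed over all probes and 1 did adjusted over the list alone, CDKN1A, an inhibitor of cyclin-dependent kinases, at 0.34 (adjusted p over all probes = 0.104), or 0.23 without knockdown 2 and 6. Of 13 apoptosis regulators 1 rose by both counts, BIK, a pro-apoptotic member of the BCL2 family, at 0.37 ± 0.06 (adjusted p = 0.0403), or 0.23 without background correction, and 12 did not pass.

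IL11 was the 1 of 20 NF-kB cytokines and inflammatory genes that rose, over all probes and adjusted over the list alone. IL1B had 0.23 (adjusted p = 0.23), or 0.11 without knockdown 2 and 6, and TNFAIP3 also had 0.23 (adjusted p = 0.296). Of 17 interferon-stimulated genes none passed over all probes and 1, HERC5, passed adjusted over the list alone, at 0.33. Among 13 NRF2 targets and metallothioneins, genes of the oxidative and metal stress response, none passed over all probes and 3 were lower adjusted over the list alone: AKR1C2 at -0.58, MT2A at -0.21 and GCLM at -0.21 (-0.13 without knockdown 2 and 6). The groups did not overlap for MT2A, but did for GCLM and for AKR1C2, whose controls ranged from 9.29 to 9.83, with knockdown 1 at 9.31. AKR1C2 and MT2A belong to gene families with similar members, and cross-hybridisation of their probes was not tested. Of the 13 genes, 9 had a log2 fold change below 0 and 4 had one above it. Those above included SLC7A11 at 0.40, detected on 2 of 6 control arrays, GCLC at 0.12 and TXNRD1 at 0.09 (-0.08 on its other probe). The median log2 fold change of that list was -0.08, and with scaling by the median alone it was 0.06, or -0.06 relative to the median of all detected probes. For this list camera gave an adjusted p of 0.0906, or an adjusted p of 0.308 with an estimated correlation. None of the 17 hypoxia and glycolysis genes, the 13 genes of the unfolded protein and integrated stress response or the 13 cholesterol biosynthesis genes passed over all probes or adjusted over the list alone; ALDOA had -0.12, PPP1R15A 0.14 and NSDHL 0.09. The medians of the hypoxia and the DNA replication lists were above 0, at 0.02 and 0.01, while camera placed both below the other genes (adjusted p = 0.870 and 0.941).

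None of the 11 genes of the RNA interference machinery and none of the 9 detected neighbours of TIMP1 on the X chromosome passed over all probes or adjusted over the list alone; AGO3 had 0.31 (adjusted p = 0.32), or 0.15 without background correction and 0.17 without knockdown 2 and 6, and RBM10 had -0.12. The dimmer probes of these genes had 0.01 for AGO3 and 0.06 for RBM10. Of the 18 ribosomal protein, 17 oxidative phosphorylation and 9 housekeeping genes, none passed either way. CYC1 had 0.13 and ACTB -0.06 on its brightest probe and 0.01 on each of its other 2, and the adjusted p of the mixed fry test for the oxidative phosphorylation list was 1.97e-09, with 10 members above and 7 below 0. Markers of other cell types were few among the detected genes. Of 4 pancreatic acinar and islet markers none passed over all probes and PRSS1, a trypsinogen, was lower at -0.19 adjusted over the list alone. None of 3 leukocyte and endothelial markers passed either way. Of 2 fibroblast and stellate cell markers, too few for a list test, none passed over all probes. PDGFRA passed adjusted over the list alone, at 0.12 on its brightest probe, while its other detected probe had 0.05. With scaling by the median alone, and relative to its shift of 0.12 in all detected probes, the medians of 22 of the 24 tested lists kept their sign; that of the mesenchymal list went from 0.02 to -0.04 and that of the cholesterol list from -0.01 to 0.01. Of the other list members named, TIMP3 had 0.11, ITGA6 0.12, KLF10 0.11 and TNFAIP3 0.12 without background correction, and TIMP2 had 0.05, KLF10 0.10 and CCN2 -0.09 without knockdown 2 and 6.

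**Figure D4:**
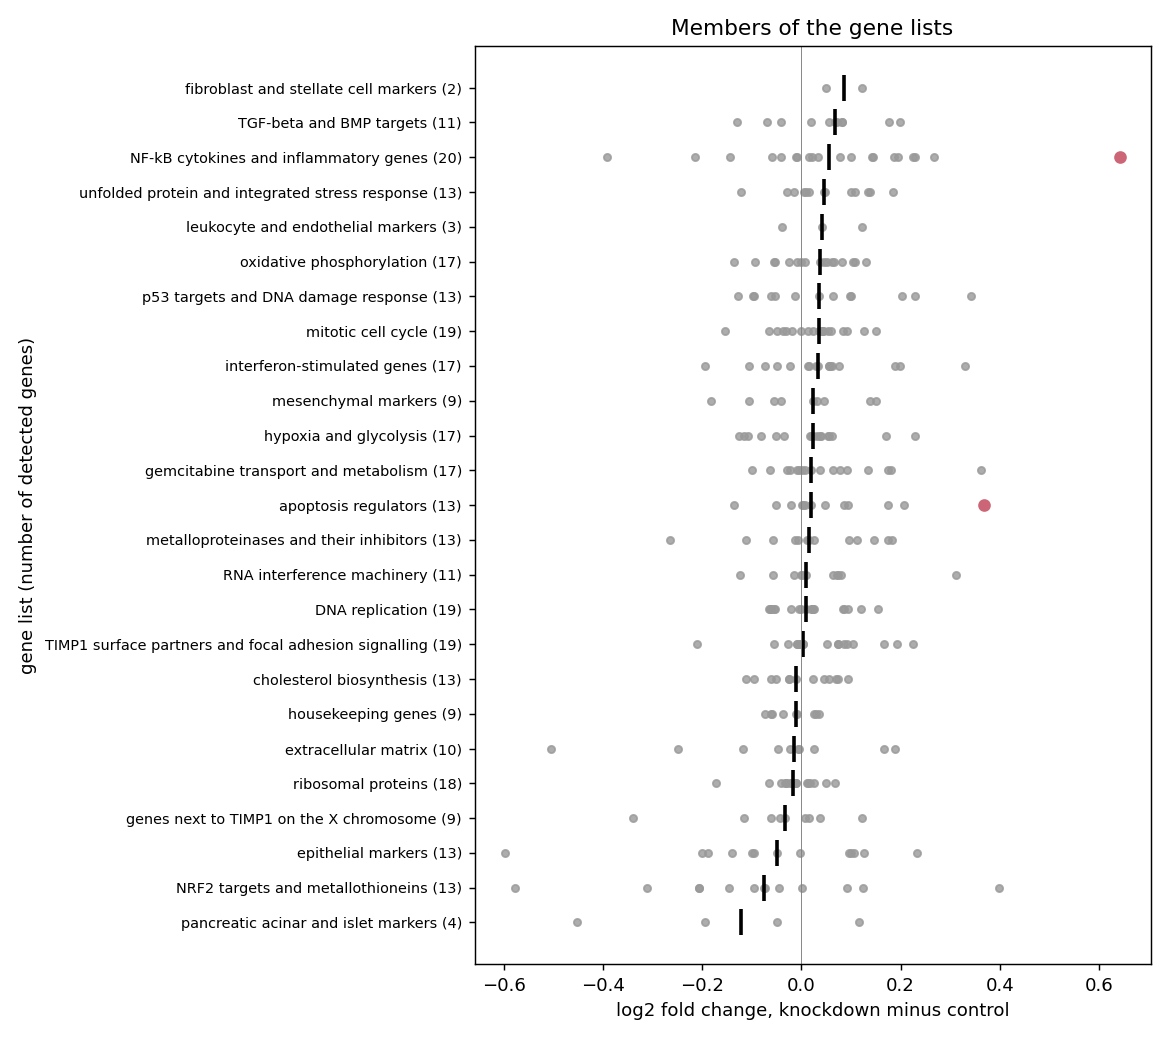
Log2 fold change (knockdown minus control) of each detected member of the 25 gene lists (grey points), with the list's median as a black bar and the number of detected genes beside its name. The 2 members past the threshold over all probes, IL11 and BIK, are the larger coloured points.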

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

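The 3 patterns weighed here and all tests of them were chosen after the values had been seen. The splits of the arrays were planned.

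The 12 arrays can be divided into 6 and 6 in 462 ways, and 100 of these, the real one included, were fitted with limma. Of these splits, 1, the real one, reached 42 probes past the threshold in 1 direction, and the highest count of any other was 2. The splits do not address a difference in handling between the groups. A chance division of the arrays is argued against as the source of the rises, though 1 in 100 is the smallest share these splits can give. The same holds for the 8 lower probes, reached by 1 of the 100 splits, with 2 the highest of the others. Likewise 1 split gave 4 probes at least 2-fold apart, with 0 the highest of the others.

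Control 6 and knockdown 1 lay between the groups. On 200 probes picked without both arrays, with the other controls at 0 and the other knockdown arrays at 1, control 6 lay at 0.43 and knockdown 1 at 0.37, while in 36 such pairs the other controls lay at -0.08 to 0.21 and the other knockdown arrays at 0.68 to 1.27. Whether these 2 labels were swapped could not be decided from these positions. Each array lay outside the range of the other group, where a swap would place it, but also outside the range of its own. An array-wide shift in detected probes is argued against for control 6, whose 15997 detected probes lay within the range of the other controls (15681 to 16565), but it may account for knockdown 1, whose 15898 were below the 16422 of the next knockdown array. A mixture of RNA or cells of both groups in these 2 samples could not be excluded: TIMP1 itself lay at 0.58 in control 6 and 0.62 in knockdown 1, but its values on the other controls spread from -0.84 to 0.23, and neither a weaker effect of the hairpin in knockdown 1 nor a drift over an order of handling, which is not given in the sources used here and would also place these 2 arrays between the groups if it followed the replicate numbers, was tested.

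Knockdown 2 and knockdown 6 stood apart from the other 10 arrays along the first principal component, at 20.9 and 30.4 against -18.6 to 10.1. The component rose with the number of detected probes (12 arrays; r = 0.869, permutation p = 0.00023, adjusted over 2 relations 0.00046; rho = 0.748, p = 0.00729, adjusted 0.0146; r = 0.637 without the 2 farthest arrays). Background of dim probes is argued against as the whole cause, because over the 5108 probes with a mean log2 intensity of at least 10 both arrays still lay apart by 2.87 times the range of the other 10. A stress response of these cultures is a candidate explanation: the stress response list had means of 0.20 and 0.16 in these arrays against at most 0.04 in the others, and it followed the component over bright probes (r = 0.896, permutation p = 0.00339; rho = 0.692, p = 0.0151; both unchanged by adjustment), but r was 0.22 without the 2 farthest arrays, so the relation rests on them. Genes of the stress list, among them ATF4, ASNS, TRIB3 and PHGDH, are themselves among the bright probes that make up the component. The permutation p-values of this relation are therefore not independent support for a stress response. In 9 of 24 lists both arrays lay above the other 10, so the shift was not specific to stress genes, and differences in RNA quality stay open as untested.

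The fall of TIMP1 by 12.5% was small for a targeted gene. Background added to the signal is argued against, since the median signal of an array was at most 1.61% of its TIMP1 signal. Normalisation is argued against too, since the mean signal before any correction changed by -14.1%. Compression of the signal of very bright probes may hide a larger fall and cannot be told apart from a weak knockdown. TIMP1 on the control arrays was within 1.15 to 1.34 times of the brightest probe. None of 336 other probes of like or greater brightness (no more than 0.25 below TIMP1 on the log2 scale) fell by more, with log2 fold changes from -0.13 to 0.14. A drift over an order of handling, which is not given in the sources used here, could give such a fall without a knockdown and was not tested.

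In 15 of 282 groups of 6 arrays tested, 1 array stood far from the other 5 by the Dixon criterion, where chance gives about 1 in 20, or 14.1. Among the controls, ITGA5 was 9.39 in control 1 (others 9.21 to 9.24), KLF10 was 7.33 in control 1 (7.49 to 7.57) and NDUFV1 was 11.20 in control 1 (11.37 to 11.40). IFI44L was 7.34 in control 2 (6.63 to 6.86), PSAT1 was 10.95 in control 4 (11.02 to 11.06), BIRC2 was 9.61 in control 5 (9.44 to 9.50) and MT2A was 13.17 in control 5 (12.97 to 13.04). Among the knockdown arrays, TNFAIP3 was 7.30 in knockdown 1 (7.70 to 7.86), SLC28A1 was 7.56 in knockdown 2 (6.86 to 6.97), GUSB was 9.75 in knockdown 3 (9.84 to 9.88) and AXL was 11.55 in knockdown 4 (11.72 to 11.78). RFC3 was 10.45 in knockdown 6 (10.22 to 10.26) and CD68 was 9.68 in knockdown 6 (9.46 to 9.52). The mean of the DNA replication list was -0.0458 in knockdown 2 (others 0.00933 to 0.0367), and that of the neighbours of TIMP1 on the X chromosome was -0.06695 in control 5 (0.026 to 0.06615).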

How the results depend on the processing

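The settings without knockdown 2 and 6 and with the number of detected probes as a covariate were chosen after seeing the data. No background correction and the authors' processed values were in effect the same setting, since both are the quantile-normalised signal, and each gave 39 calls. The counts of alternatives hold both. The log2 fold change of TIMP1 was between -0.23 and -0.12 over 26 alternatives; with median scaling it was -0.12 and no longer past the exact test. Of 452 recomputed values of the 17 genes with the largest rises and falls, 256 were no longer past the threshold; their direction could not turn when arrays were left out, since they were chosen for groups that do not overlap. Of 3689 values of genes and lists, 3394 stayed on their side of the threshold, 273 no longer passed, 22 newly passed and 0 reversed; 80 uncalled values changed sign. The 42 higher and 8 lower probes became 26 and 6 with cyclic loess, 10 and 1 with median scaling, 9 and 2 with no detection filter, and 43 and 25 with the stricter filter (21 shared with the 50). An intensity trend with a robust fit gave 90 in all (37 shared), 33 of them lower, and a threshold of 0.01 gave 1 and 0. The Wilcoxon test gave 0 and 0 (2025 probes at an unadjusted p under 0.05), and it cannot give a p below 0.00216. Without knockdown 2 and 6 there were 1 higher and 1 lower probe; the median absolute log2 fold change of the 50 probes was 0.38 in place of 0.40. With the covariate there were 0 and 0, and the median standard error of the 50 probes rose from 0.063 to 0.076 while their median change went from 0.40 to 0.37. Leaving out 1 array gave 1 to 112 higher probes and 0 to 33 lower ones; the probe of SPHK1 was the 1 call kept in all 12 of these fits. The 4 probes at least 2-fold higher became 0 with no background correction, the larger offset, the authors' processed values, the stricter filter, the Wilcoxon test, a threshold of 0.01, the covariate and without knockdown 2 and 6, 1 with no detection filter, and 0 to 5 leaving out 1 array. The 0 shifted lists became 1, the NRF2 and metallothionein list, with the stricter filter, with the trend and robust fit and with the mean of all probes of a gene, and 0 to 1 leaving out 1 array (1 without knockdown 3); with an estimated correlation its adjusted p was 0.308. The cause of these changes was not tested, except that fewer arrays leave fewer degrees of freedom. With the replicate number as a block there were 22 higher and 6 lower probes, 17 shared with the 50. The numbers were not taken to pair the arrays: deviations of same-numbered arrays correlated at over 0.1 in 3 of 6 pairs, and 1 of 6 controls correlated best with the knockdown array of its number. A slide as a block was not run, since the files used here name no slide. Dim probes are limited by the background: SPHK1 was detected on 0 of 6 control arrays, and its rise is given as at least 1.10-fold.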

Other observations

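The tests of the epidermal differentiation and S100 lists and the choice of the genes named next were made after the values had been seen. Outside the named genes, the smallest p was that of SPHK1, a kinase that makes sphingosine 1-phosphate, which was at least 1.10-fold higher in the knockdown (limma adjusted p = 0.00557). PAPSS2, an enzyme that makes the sulfate donor of the cell, rose by 0.47 on the log2 scale and AACS, a ketone body ligase, by 0.31. CXCL16, a chemokine, rose by 0.39, RIPK2, a kinase downstream of NOD receptors, by 0.30 and SAA1, an acute phase protein, by 0.35. CD83, a surface protein best known from dendritic cells, had 1 probe that rose by 0.40 and was detected on 4 of 6 control arrays, while its brighter probe had -0.03 (adjusted p = 0.867).

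SPRR2A, SPRR2D, SPRR2F, S100A8 and S100A9 rose, and all lie on chromosome 1. A general rise of epidermal differentiation genes or of S100 genes was therefore a hypothesis to test. The criteria set for both lists, which used the SD over all members with the risers included, decided neither. Of 12 detected epidermal differentiation genes 3 rose over all probes, and 4 rose and 1 fell adjusted over the list alone; all 12 had a median log2 fold change of 0.0914 with an SD of 0.48 between members, and the 9 without those 3 lay between -0.60 and 0.34. GRHL3 had -0.36 and CRABP2 0.34. With all their members each of the 2 lists had a camera adjusted p of 0.0309, or an adjusted p of 0.0991 with an estimated correlation. These p-values include the risers that prompted the lists, so they cannot show a rise beyond those genes. Without the genes past the threshold, the other 9 epidermal differentiation genes had a median of 0.01 and an SD of 0.29, with 6 above 0 and 3 below. The other 9 S100 genes had a median of 0.02 and an SD of 0.10, with 5 above 0 and 4 below. For each of these remainders the camera adjusted p was 0.737. These values argue against a rise shared by the other 9 S100 genes, which had log2 fold changes of at most 0.12. For the epidermal differentiation genes the SD was too wide to decide. Of 11 detected S100 genes, S100A8 at 1.06 and S100A9 at 0.93 rose, and the other 9 lay between -0.22 and 0.12; the median of all 11 was 0.0267, with an SD of 0.41 between members.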
